A study of Bos grunniens with 6 samples.

How the data were processed

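RNA was measured in 6 samples of cultured yak (Bos grunniens) skin cells, 3 of dermal papilla cells (DPC) and 3 of hair matrix cells (HMC). Per the labels' protocols, total RNA was extracted with Trizol and stranded mRNA libraries were prepared with a TruSeq kit. The submitters' processing notes name Trimmomatic, HISAT2 2.2.1.0 and DESeq 1.20.0 without giving their roles. The read counter, the genome build and the annotation release are not given in the sources used here, so no coordinates are printed and gene identifiers stand as the table gives them. The table deposited by the authors holds FPKM, a unit of fragments scaled to gene length and to mapped fragments, for 15646 genes, with 1 column per sample. The series title also names miRNA, which was not analysed here.

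FPKM already corrects for gene length and for the total number of mapped fragments, but not for a difference in RNA composition between cell types. The values of each gene were whole multiples of a gene-specific step in every library, for 100% of genes within a relative tolerance of 1e-09, so whole reads had been counted. The recovered reads summed to between 13.1 and 14.0 M per library (M, mega). They are known only up to a common factor per gene, so these sums are lower limits of the depth. No gene in the table was at 0 in all 6 libraries.

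The table pairs identifiers with gene symbols, many of them older ones. Of 889 distinct symbols in 32 gene lists of skin cell types and pathways, 443 matched a symbol in the table directly. A further 294 were matched after the data were examined, through older symbols of the same gene read against the table's own annotation, and 152 were not matched and are not analysed here. The row called SMO carries the annotation of spermine oxidase and the row called PDK1 that of another kinase, and both stayed in the direct match as written but not in the match through older symbols. The row called CCN1 carries no annotation, so its identity rests on the symbol alone. In the text an older symbol follows the current one in parentheses. Where several rows shared a symbol, the one with the higher mean FPKM was taken. Members of gene families such as keratins, actins and ribosomal proteins may share reads, and how the authors' counter treated those is not given in the sources used here, so their single values are uncertain.

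Groups were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a trended prior variance, for genes with a mean of at least 0.5 FPKM over the 6 samples. The direction is DPC minus HMC, the test is two-sided, and p was adjusted over all genes tested by the Benjamini-Hochberg method, with 0.05 as the threshold. A log2 difference on this scale understates the change of genes with low values. A size limit of 2-fold was applied as a second count. Gene lists with 5 or more tested members were compared with all other genes by camera, with a preset correlation of 0.01, and again with an estimated correlation. In the estimated form camera uses only the residual degrees of freedom of the 6 samples, so few lists or terms can pass. Each list was also tested by fry, which asks whether the genes of a list move at all. Annotation terms of the table with 15 to 500 tested genes were tested by camera with the preset correlation, and again with an estimated one. The other computations used Python 3.11.15 with numpy 2.4.6 and pandas 2.3.3, and figures were drawn with matplotlib 3.10.9.

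The genes named are, by a rule, the 8 with the largest difference in each direction whose values do not overlap between groups and that carry a symbol, for each list up to 3 members of largest difference and the most abundant one, and a fixed set of markers. SOX2 and MKI67 belong to that set and are not analysed here, and some genes that the rule selects are not reported here. Members named as the exceptions of a list, and all genes given under older symbols outside the fixed set, were chosen after their values were seen. The groups, lists, tests, naming rule and most alternatives were fixed before the data were examined.

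The procedure was tested on a simulated table drawn from the mean reads and library sizes of the real samples, with 200 changed genes among 11870 tested. It recovered 50% of the genes changed 1.25-fold, 84% at 1.5-fold, 94% at 2-fold and 100% at 4-fold. It also called 16 unchanged genes, 8.89% of its calls, and camera called 0 of 100 random lists. The simulated genes varied independently, with a shared dispersion and few changes, whereas 75.9% of genes were called in the real data. These rates hold for that simpler setting only. The count of random lists gives no error rate of camera for lists of correlated genes.

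The alternatives tried were a pseudocount of 0.1, no filter on low values, a filter at 5 FPKM, rescaling by median-of-ratios size factors, quantile normalization, a prior variance without trend, the replicate number as a block, and each replicate left out in turn. Chosen after the data were examined were limma's voom on the recovered reads, older symbols added to the lists, and the counts of lists and terms called with an estimated correlation. The labels call the samples biological replicates but do not say whether they came from separate animals, so p-values measure the spread between these cultures, which may be smaller than that between animals.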

Results

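Dermal papilla cells (DPC) are mesenchymal cells at the base of the hair follicle that signal to its epithelium, and hair matrix cells (HMC) are the epithelial cells around the papilla that divide to form the hair. Both were isolated from yak skin and grown in a shared medium with 10% serum, EGF (20 ng/mL) and IGF1 (10 ng/mL), and mRNA was sequenced from 3 cultures of each. The recovered reads came to between 13.1 and 13.4 M in the DPC libraries and between 13.7 and 14.0 M in the HMC libraries (M, mega). Between 13541 and 13562 genes lay above 0 in DPC and between 13882 and 13942 in HMC. The FPKM of a library summed to between 548897 and 554803 in DPC and between 647963 and 651773 in HMC. The 10 genes with most reads took 13.4 to 14.0% of recovered reads in DPC and 8.56 to 8.59% in HMC, while the top 10 by FPKM took 13.96 to 14.4% of FPKM in DPC and 14.2 to 14.3% in HMC. Replicates were not copies of each other, since the chi-square of their recovered reads was between 2.63 and 5.74 per gene, above the value of 1 that counting error alone gives. A first principal component with 97.4% of the variance separated DPC from HMC, and HMC replicate 3 lay at 13.89 on the second component, which held 0.8%, against -9.32 and -4.28 for the other HMC libraries.

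The comparison of DPC with HMC asks which mRNAs distinguish the cell types of the yak hair follicle. DPC had higher mRNA of the collagen COL1A1, the actin ACTA2 and the transcription factor TWIST1, and HMC had higher mRNA of the keratins KRT7 and KRT8, the junction protein CDH1 and the lipid enzyme FASN. The largest difference toward DPC was that of somatostatin (SST, ENSBGRG00000001258), a peptide hormone that inhibits secretion in endocrine and gut cells. It stood at 5811 ± 102 FPKM in DPC and 6.78 ± 1.92 FPKM in HMC (SD, n = 3 each; log2 difference 9.58, SE 0.16, limma adjusted p = 4.89e-10). Among the largest toward HMC was that of KRT7, a keratin of simple epithelia, at 3686 ± 13.6 FPKM in HMC and 9.08 ± 1.41 FPKM in DPC (SD, n = 3 each; log2 difference -8.52, limma adjusted p = 5.81e-11). In limma, 9020 of 11883 genes passed the adjusted threshold, 3531 higher in DPC and 5489 higher in HMC, and 3223 of them differed at least 2-fold, 1306 toward DPC and 1917 toward HMC. The split between directions depended on scaling, since 39.1% of the calls were higher in DPC with FPKM as deposited, 49% after median-of-ratios rescaling and 53.8% after quantile normalization. The median log2 difference of all tested genes was -0.15, -0.02 and 0.05 under the same scalings, so small differences of either sign are read against that shift.

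The genes next to SST were the heparin-binding growth factor pleiotrophin (PTN) at 416 ± 1.95 FPKM in DPC and 2.30 ± 1.08 FPKM in HMC, PRSP, the mesodermal transcription factor TWIST1 (TWIST), PS20, the smooth muscle actin gene ACTG2 (ACTA3), the fibrillar collagen gene COL11A1 (COLL6) and the basement membrane gene NID1 (NID). Their log2 differences lay between 7.03 and 6.24. TWIST1 stood at 380 ± 3.72 FPKM in DPC and 2.90 ± 1.32 FPKM in HMC (SD, n = 3 each). Other large differences toward HMC were those of the secreted protease inhibitor WFDC2, KRT8, KRT18 (PIG46), LY6G6C, the membrane protease matriptase (ST14, in the table PRSS14) and SP001LA. KRT8 stood at 3352 ± 106 FPKM and its partner KRT18 at 982 ± 6.05 FPKM in HMC, against 8.56 ± 1.46 and 1.83 ± 0.290 FPKM in DPC (SD, n = 3 each). WFDC2 stood at 683 ± 45.2 FPKM in HMC and 0.911 ± 0.239 FPKM in DPC.

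**Figure D1:**
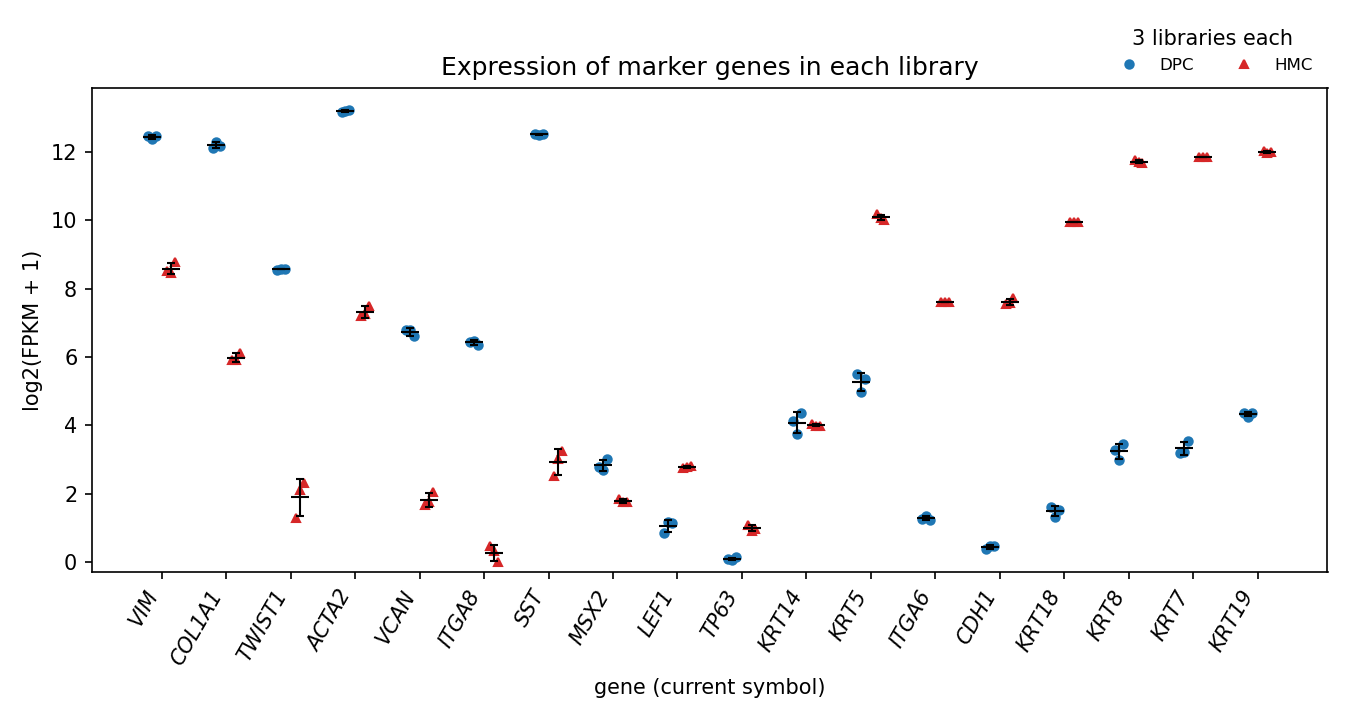
Expression of 18 marker genes as log2(FPKM + 1) on the vertical axis, with 1 point per library, circles for DPC and triangles for HMC (n = 3 each), and a black bar for the mean with its SD. VIM, COL1A1, TWIST1, ACTA2, VCAN, ITGA8 and SST lie higher in DPC, KRT5, ITGA6, CDH1, KRT18, KRT8, KRT7 and KRT19 lie higher in HMC, and KRT14 overlaps.

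Mesenchymal markers were higher in DPC. Counts of list members refer to genes that the table gives under their current symbol, unless older symbols are named. Of 22 tested members of the fibroblast and mesenchyme list, 21 were higher in DPC, all of them at least 2-fold. The type I collagen gene COL1A1 stood at 4672 ± 299 FPKM in DPC and 62.4 ± 5.70 FPKM in HMC (SD, n = 3 each; log2 difference 6.20). The cadherin CDH11 and the matrix protein fibulin 1 (FBLN1) had log2 differences of 5.80 and 5.78. The most abundant member was the intermediate filament vimentin (VIM), at 5517 ± 231 FPKM in DPC and 384 ± 43.5 FPKM in HMC. The exception was fibronectin (FN1), at 1275 ± 32.2 FPKM in DPC and 1571 ± 88.5 FPKM in HMC, and it did not pass after quantile normalization. The list was past the camera threshold (adjusted p = 2.26e-13) but not with an estimated correlation (adjusted p = 0.159 with an estimated correlation). In the list of proteoglycans and matricellular proteins, 8 of 9 tested members were higher in DPC, among them fibulins FBLN2 and FBLN5 and the collagen-binding proteoglycan fibromodulin (FMOD), and the camera adjusted p was 5.39e-05 (adjusted p = 0.159 with an estimated correlation). The member that went the other way, the row called CCN1, which carries no annotation in the table, differed little, with a log2 difference of -0.12 that became 0.04 after median-of-ratios rescaling and 0.11 after quantile normalization.

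Most contractile genes were also higher in DPC. Smooth muscle alpha-actin (ACTA2, in the table ACTSA) stood at 9321 ± 181 FPKM in DPC and 159 ± 18.6 FPKM in HMC (SD, n = 3 each; log2 difference 5.87). Of 10 tested members of the contractile and smooth muscle list, 8 were higher in DPC, with log2 differences of 5.34 for both tropomyosin 2 (TPM2) and calponin (CNN1). The most abundant of them, CSRP1, differed little, at 714 FPKM in DPC and 639 FPKM in HMC. TAGLN, under the older symbol SM22, was abundant in both, at 2952 FPKM in DPC and 1584 FPKM in HMC. Calponin 2 (CNN2) and myocardin (MYOCD), a coactivator of smooth muscle genes, were higher in HMC, MYOCD at 29.0 FPKM there and 0.023 FPKM in DPC. The camera adjusted p was 0.00509 (adjusted p = 0.159 with an estimated correlation).

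The dermal papilla signature was divided between the cell types. Of 16 tested members, 8 were higher in DPC and 8 in HMC. The integrin ITGA8, a papilla and mesenchyme marker, stood at 85.1 ± 3.78 FPKM in DPC and 0.219 ± 0.201 FPKM in HMC (SD, n = 3 each), and the WNT agonist RSPO3 at 58.1 ± 2.14 and 0.522 ± 0.255 FPKM. The BMP antagonist noggin (NOG) had a log2 difference of 4.28. Versican (VCAN, in the table CSPG2), a proteoglycan used as a papilla marker, stood at 105 ± 7.48 FPKM in DPC and 2.58 ± 0.518 FPKM in HMC. The activin antagonist follistatin (FST) was higher in HMC, at 1944 ± 14.6 FPKM against 209 ± 1.53 FPKM. So was the WNT-responsive factor LEF1, at 5.91 ± 0.168 FPKM against 1.09 ± 0.257 FPKM. Alkaline phosphatase (ALPL), a papilla marker in tissue, was near 0 in both, with means of 0.014 FPKM in DPC and 0.019 FPKM in HMC. The same held for CORIN (CRN), with means of 0.058 and 0.160 FPKM. The camera test leaned toward DPC (adjusted p = 0.627), the mean log2 difference was 0.60 and the median was -0.03.

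Epithelial genes were higher in HMC. Of 24 tested members of the basal keratinocyte and epithelium list, 23 were higher in HMC, each at least 2-fold. KRT19 was the most abundant keratin of the list, at 4090 FPKM in HMC and 19.1 FPKM in DPC. The basal keratin KRT5 stood at 1083 ± 59.8 FPKM in HMC and 38.1 ± 7.08 FPKM in DPC (SD, n = 3 each). E-cadherin (CDH1) stood at 195 ± 12.6 against 0.368 ± 0.052 FPKM, and the basal integrin ITGA6 at 193 ± 0.562 against 1.45 ± 0.110 FPKM. KRT14, the usual partner of KRT5, did not pass, with 16.2 ± 3.63 FPKM in DPC and 14.998 ± 0.330 FPKM in HMC (limma adjusted p = 0.605). The basal transcription factor TP63 (KET) was low, at 0.992 ± 0.129 FPKM in HMC and 0.069 ± 0.031 FPKM in DPC. The list was past the camera threshold (adjusted p = 6.19e-10), and the adjusted p = 0.0682 with an estimated correlation.

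Few genes of the hair itself were among those tested. Of 50 genes listed for the hair matrix and hair shaft, 9 were tested, 6 higher in HMC and 2 in DPC, with a camera adjusted p of 0.37. SOX9, a factor of follicle epithelium, stood at 34.1 FPKM in HMC and 0.197 FPKM in DPC, GATA3 had a log2 difference of -2.83, and the thyroid hormone binding protein CRYM was higher in DPC by 2.69. MSX2, a factor of the hair matrix, was higher in DPC, at 6.16 ± 0.838 against 2.47 ± 0.138 FPKM (SD, n = 3 each). MSX1 stood at 21.0 FPKM in DPC and 19.7 FPKM in HMC. HOXC13 (HOX3G), a regulator of hair keratins, stood at 0.767 ± 0.249 and 0.665 ± 0.215 FPKM and did not pass (limma adjusted p = 0.601). In the keratinocyte differentiation list, 3 of 6 tested members were higher in HMC and 1 in DPC (camera adjusted p = 0.886), while the annotation term of that name had 15 of 17 genes higher in HMC (adjusted p = 0.0171, and adjusted p = 0.776 with an estimated correlation). KRT80 stood out there at 537 ± 24.9 FPKM in HMC and 2.83 ± 0.627 FPKM in DPC.

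Markers of other skin cells were few among the tested genes. Endoglin (ENG) was the one tested endothelial gene under a current symbol, at 60.8 FPKM in DPC and 1.96 FPKM in HMC. Among 4 endothelial genes with older symbols included, 3 were higher in DPC and 1, VWF (F8VWF), in HMC. Of 2 melanocyte genes, both were higher in HMC, the endothelin receptor EDNRB at 64.7 FPKM against 0.295 FPKM and SOX10 at 1.42 FPKM against 0. With older symbols added 3 of 5 melanocyte genes were higher in HMC and 1, MITF (BHLHE32), in DPC. Of 4 immune genes, AIF1 and CD14 were higher in HMC and LAPTM5 in DPC. Of 3 Schwann and neural genes, PMP22 and S100B were higher in DPC and SOX10 in HMC. Of 2 pericyte genes, NDUFA4L2 was higher in DPC and NOTCH3 in HMC, and with older symbols added 3 of 6 were higher in each cell type. All 3 tested sebaceous and sweat gland genes were higher in HMC, and FASN and SCD among them belong to fatty acid synthesis in general. With older symbols added 4 of 6 were, and PPARG (NR1C3) and SOAT1 (ACAT) were higher in DPC. In the adipocyte list 5 of 7 were higher in DPC and 2 in HMC (camera adjusted p = 0.14), and with older symbols added 8 of 10 were higher in DPC (adjusted p = 0.01, and adjusted p = 0.192 with an estimated correlation). Of the skeletal muscle progenitor genes only ITGA7 (UNQ406/PRO768) was tested, under an older symbol, at 39.1 FPKM in HMC and 0.136 FPKM in DPC.

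**Figure D2:**
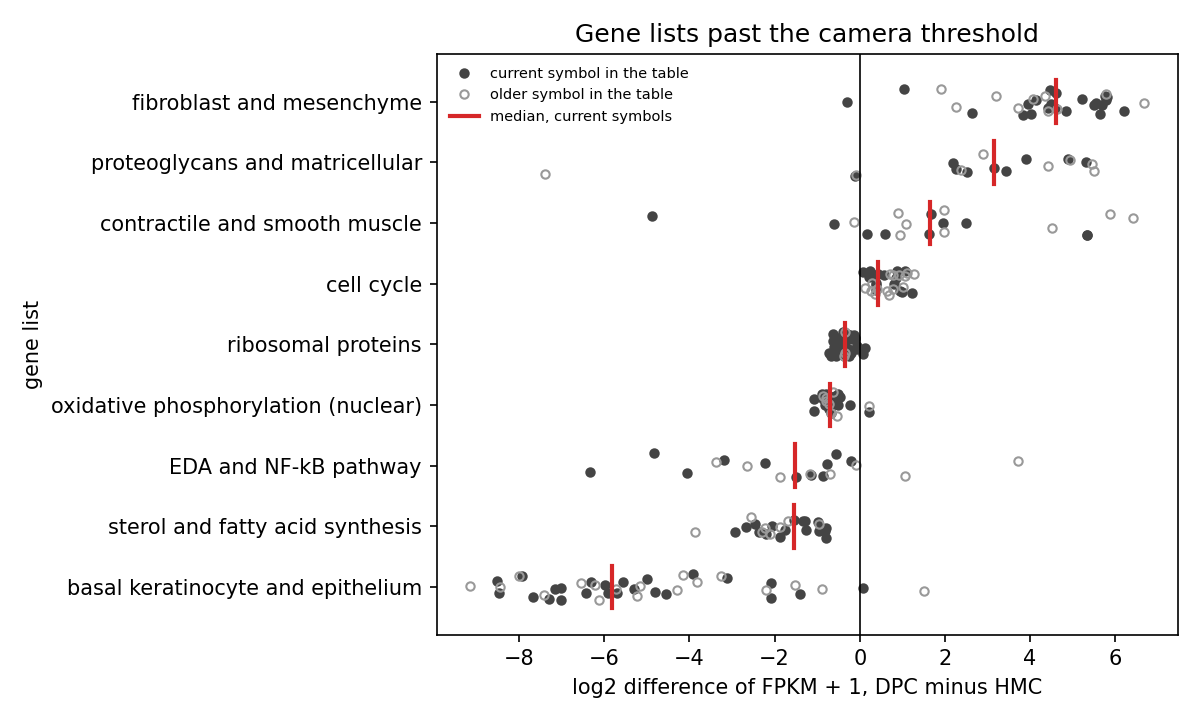
Log2 differences (DPC minus HMC, horizontal axis) of the members of the 9 gene lists past the camera threshold, 1 point per gene, filled where the table uses the current symbol and open where it uses an older one, with a red bar at the median of the filled points. Medians run from 4.60 for fibroblast and mesenchyme to -5.81 for basal keratinocyte and epithelium.

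Most genes of the NF-kB pathway, which drives inflammatory cytokines, were higher in HMC. Of 11 tested members of the EDA and NF-kB list, 10 were higher in HMC. The cytokine LIF stood at 263 FPKM in HMC and 2.28 FPKM in DPC, IL6 at 229 against 7.08 FPKM and IL1A at 46.9 against 1.89 FPKM. The camera adjusted p was 0.00164 (adjusted p = 0.245 with an estimated correlation). With older symbols added 15 of 19 were higher in HMC and 2 in DPC (camera adjusted p = 0.00675, and adjusted p = 0.465 with an estimated correlation). Those 2 were the chemokine CCL2 (SCYA2), at 140 FPKM in DPC and 9.88 FPKM in HMC, and EDA (ED1), at 1.76 and 0.304 FPKM. Of 16 tested interferon response genes, 13 were higher in HMC, with log2 differences of -3.18 for CMPK2 and -3.16 for the peptide transporter TAP1, and IRF1 was higher in DPC. That list missed the camera threshold (adjusted p = 0.0633), and it passed without HMC replicate 2 (adjusted p = 0.00755, and adjusted p = 0.25 with an estimated correlation), as it did under several other settings. Of 12 immediate early genes, 8 were higher in HMC and 2 in DPC (camera adjusted p = 0.171), and with older symbols added 12 and 8 of 22 (adjusted p = 0.738), with KLF4 (EZF) among those higher in DPC.

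Growth factor and morphogen pathways held members of both directions. Of 23 tested genes of FGF, EGF and IGF signalling, 12 were higher in HMC and 9 in DPC (camera adjusted p = 0.896). The EGF receptor ligand amphiregulin (AREG) stood at 230 FPKM in HMC and 0.330 FPKM in DPC, PDGFB at 142 against 0.278 FPKM, and the IGF binding protein IGFBP4 at 12.03 FPKM in HMC and 327 FPKM in DPC. Of 25 WNT pathway genes, 12 were higher in each cell type (camera adjusted p = 0.586). SFRP4, a secreted WNT antagonist, and RSPO3 had log2 differences of 5.56 and 5.29, and the WNT receptor FZD1 one of 3.63. The mean log2 difference of that list was 0 and its median 0.20, the camera test leaned toward DPC and fry toward HMC. Of 21 BMP and TGF-beta genes, 11 were higher in DPC and 10 in HMC (camera adjusted p = 0.183). With older symbols added 20 of 33 were higher in DPC and 13 in HMC (adjusted p = 0.0139, and adjusted p = 0.172 with an estimated correlation). Among them were LTBP2 at 237 FPKM in DPC against 9.99 FPKM and the inhibin subunit INHBB at 37.5 FPKM in HMC against 1.14 FPKM. Of 12 Notch and Hedgehog entries, 1 of them the spermine oxidase row called SMO, 7 were higher in HMC and 5 in DPC (camera adjusted p = 0.896). With older symbols added and that row left out, 8 of 21 were higher in HMC and 11 in DPC (adjusted p = 0.111). The fringe enzymes of that list went opposite ways, MFNG with -4.82 and LFNG with 3.47. Under current symbols its median of -0.66 and mean of -0.29 were below 0 while the camera test leaned toward DPC. Of 5 HOX and limb-position genes, 3 were higher in DPC, EN1 the most with 42.8 FPKM against 1.86 FPKM (camera adjusted p = 0.14).

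Matrix genes beyond the fibroblast list went both ways. Of 10 tested collagens and basement membrane genes, 6 were higher in DPC and 3 in HMC. The type IV collagen chains COL4A1 and COL4A2 had log2 differences of 4.65 and 4.74, while COL4A4 and COL4A3 were higher in HMC. The camera adjusted p was 0.0645, and it was 0.000463 among genes of at least 5 FPKM (adjusted p = 0.12 with an estimated correlation). With older symbols added 12 of 21 were higher in DPC and 7 in HMC (camera adjusted p = 0.0206, and adjusted p = 0.407 with an estimated correlation). With voom the camera adjusted p was 0.0195 (adjusted p = 0.218 with an estimated correlation). Of 21 matrix remodelling enzymes, 11 were higher in DPC and 9 in HMC (camera adjusted p = 0.171). This list passed with older symbols added (adjusted p = 0.0388, and adjusted p = 0.18 with an estimated correlation). Cathepsin K (CTSK) stood at 725 ± 20.2 FPKM in DPC and 13.7 ± 1.49 FPKM in HMC (SD, n = 3 each), and the gelatinase MMP9 at 371 ± 75.1 FPKM in HMC and 3.101 ± 0.643 FPKM in DPC. The plasminogen activator PLAU was higher in HMC, with a log2 difference of -4.36.

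Cell cycle genes were higher in DPC by small factors. Of 17 tested members, 16 were higher in DPC, 2 of them at least 2-fold, with a median log2 difference of 0.43. Topoisomerase TOP2A stood at 39.9 ± 1.61 FPKM in DPC and 16.6 ± 3.06 FPKM in HMC (SD, n = 3 each), and the replication helicase subunit MCM3 had a log2 difference of 1.05. In HMC replicates 1, 2 and 3 TOP2A stood at 13.9, 16.1 and 19.9 FPKM and MCM3 at 26.1, 28.2 and 33.2 FPKM, so HMC replicate 3, which lay apart on the second component, was closest to DPC for these genes. The mitotic activator CDC20 did not pass, at 68.9 ± 1.28 and 64.9 ± 5.43 FPKM. The camera adjusted p was 5.81e-05 (adjusted p = 0.37 with an estimated correlation). In the list of senescence and cell cycle arrest 5 of 7 members were higher in DPC and 2 in HMC, the p53 regulator MDM2 and CDKN2B (camera adjusted p = 0.171). Older symbols made this 7 of 11 higher in DPC and 4 in HMC, p21 (CDKN1A, in the table CIP1) among the latter (camera adjusted p = 0.332). The mean log2 difference of this list then moved from 0.26 to -0.28, and the direction of fry turned from DPC to HMC.

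Lipid synthesis and respiration genes were higher in HMC. All 17 tested members of the sterol and fatty acid list were higher in HMC, 12 at least 2-fold. Fatty acid synthase (FASN) stood at 190 ± 5.99 FPKM in HMC and 24.2 ± 0.866 FPKM in DPC (SD, n = 3 each), and INSIG1 and LSS had log2 differences of -2.67 and -2.45. The camera adjusted p was 1.37e-05 (adjusted p = 0.0835 with an estimated correlation). Of 19 nuclear oxidative phosphorylation genes, 17 were higher in HMC, with a median log2 difference of -0.69, and COX5A led with -1.08. The camera adjusted p was 0.00116 (adjusted p = 0.146 with an estimated correlation). Of 36 ribosomal protein genes, 31 were higher in HMC with FPKM as deposited, with a median of -0.34 and a camera adjusted p of 0.000457 (adjusted p = 0.245 with an estimated correlation). After median-of-ratios rescaling 22 of them were higher in HMC and 1 in DPC, and after quantile normalization 18 and 4. Relative to the median of all genes, the ribosomal median was -0.19, -0.17 and -0.15 under these scalings, that of oxidative phosphorylation -0.53, -0.51 and -0.51, and that of the cell cycle list 0.59, 0.60 and 0.63. Of 17 glycolysis and hypoxia entries, with the misnamed PDK1 row among them, 9 were higher in HMC and 6 in DPC (camera adjusted p = 0.896), and of the glucose transporters SLC2A1 was higher in HMC, at 290 against 24.7 FPKM, and SLC2A3 in DPC by 2.67. Of 14 genes of the unfolded protein response and heat shock, 7 were higher in HMC and 6 in DPC (camera adjusted p = 0.896). The median of -0.26 and mean of -0.05 of that list were below 0 while the test leaned toward DPC, and TRIB3, a kinase-like stress gene, was higher in DPC by 2.69.

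Of 25 gene lists with enough members, 9 passed camera with the preset correlation, 4 toward DPC and 5 toward HMC, and 0 passed with an estimated one. The sterol and fatty acid list, with an estimated correlation of -0.049, lost its call too, so correlation alone does not explain the losses. Fry, which does not compare a list with other genes, gave an adjusted p under 0.05 for 23 of the 25 lists in 1 direction and for all 25 in either direction. Adjusted over the list alone, the counts of members past the threshold stayed as given for every list but the WNT pathway, where 13 members instead of 12 were higher in DPC.

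Among 1566 annotation terms of the table, 48 passed camera, 27 toward DPC and 21 toward HMC. The term of lowest p toward DPC was collagen-containing extracellular matrix, with 51 of 73 genes higher in DPC and 20 in HMC (adjusted p = 2.4e-06), followed by endoplasmic reticulum lumen, the site of collagen folding, with 58 of 95 genes. Embryonic skeletal system morphogenesis, a term rich in HOX genes, had 20 of 27 genes higher in DPC (adjusted p = 0.000825). Toward HMC the term of lowest p was oxidative phosphorylation, with 88 of 114 genes higher in HMC (adjusted p = 0.000471). Cholesterol biosynthetic process followed with 23 of 25 genes (adjusted p = 0.00157), and desmosome, the junction that joins epithelial cells, had 13 of 16. The proteasome had 33 of 41 genes higher in HMC, with a median log2 difference of -0.43. With an estimated correlation 0 of the 1566 terms passed (adjusted p = 0.776 with an estimated correlation for every term named here). This does not show that correlation between genes made the calls. The estimated correlation of oxidative phosphorylation was -0.006, below the preset 0.01. Its unadjusted camera p still moved from 1.2e-06 to 0.00211, as the estimated form has few degrees of freedom.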

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

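The alternatives below were all planned except 3, chosen after the data were examined. These were voom on recovered reads, older symbols added to the lists, and the counts of lists and terms called with an estimated correlation. The estimated correlation itself was planned for the lists and for the named terms. The count of genes past the adjusted threshold stayed within 1.5 times of 9020 under every alternative run, from 6808 among genes of at least 5 FPKM to 9851 without a filter, and from 8554 to 8751 with 1 replicate left out. The 2-fold count ran from 2170 to 3830 against 3223. The number of lists past camera was 9, and it moved to 15 with older symbols added and to 0 with an estimated correlation. After quantile normalization 1 list passed with an estimated correlation, basal keratinocyte and epithelium (adjusted p = 0.0286). The number of terms moved from 48 to 0 with an estimated correlation. No paired structure was seen, since deviations of same-numbered libraries correlated at 0.023, 0.034 and 0.006 across genes. The pairs numbered 1 and 2 correlated best with their own number, and neither library numbered 3 did. The replicate block gave 8924 genes, 3224 at 2-fold, 10 lists and 50 terms.

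Lists that reversed were past the threshold in neither setting: FGF, EGF and IGF signalling without a filter (adjusted p = 0.827), glycolysis among genes of at least 5 FPKM (0.841), Notch and Hedgehog after median-of-ratios rescaling (0.915) and quantile normalization (0.938), the dermal papilla signature and the WNT pathway after quantile normalization (0.985 each), and the unfolded protein list with older symbols (0.676). With the preset correlation, a list outside the threshold came past it in 16 further cases and in 0 cases was one lost. The interferon list did so with adjusted p from 0.00755 without HMC replicate 2 to 0.044 with older symbols (adjusted p = 0.25 and 0.635 with an estimated correlation). The adipocyte list did so without a filter (adjusted p = 0.0466, and adjusted p = 0.289 with an estimated correlation), and matrix remodelling enzymes among genes of at least 5 FPKM (adjusted p = 0.0473, and adjusted p = 0.199 with an estimated correlation). Of single genes, CCN1 reversed under both rescalings (0.035 and 0.107), and it passed toward DPC after quantile normalization (limma adjusted p = 0.0425). Also reversed were KRT14 without DPC replicate 3 (-0.061), and HOXC13 without DPC replicate 3 (-0.025) or HMC replicate 3 (-0.019), against 0.17 without DPC replicate 2. KRT14 passed without DPC replicate 2 (log2 difference 0.25, limma adjusted p = 0.0347). MSX1 (0.23 and 0.30) and CDC20 (0.24 and 0.38) passed toward DPC under both rescalings, CDC20 also without HMC replicate 3. In 9 cases a named gene lost its call, 5 of them RPL24 and 1 FN1. The cause was not tested in any of these. Genes with few reads limit the rest: 997 genes were above 0 in 1 library only.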

Other observations

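All tests in this part were chosen after the results were seen. Genes of antigen presentation by MHC class II, the surface molecules that show peptides to T cells, were higher in HMC than in DPC. The class II chaperone CD74 (DHLAG) stood at 409 ± 10.5 FPKM in HMC and 0.729 ± 0.311 FPKM in DPC (SD, n = 3 each). The chain genes BOLA-DQB, HLA-DXA and HLA-DRA1, as the table names them, stood at 89.6, 37.1 and 23.6 FPKM in HMC, and the peptide loading genes DMA and DMB at 48.4 and 10.97 FPKM, against 2.53 and 0.681 FPKM in DPC. CIITA (MHC2TA), the coactivator that switches class II genes on, stood at 4.27 ± 0.373 FPKM in HMC and 0.043 ± 0.024 FPKM in DPC. All 7 were higher in HMC, with limma adjusted p between 1.54e-10 and 5.86e-08. Some genes that respond to interferon differed between the HMC libraries, and others, such as TAP1 and PSMB8, hardly did. ISG15 (G1P2) stood at 30.1, 10.2 and 43.3 FPKM in HMC replicates 1, 2 and 3, MX2 at 12.1, 4.10 and 18.0 FPKM and RSAD2 at 16.3, 1.83 and 3.44 FPKM, while TAP1 stood at 29.96, 28.8 and 31.9 FPKM and PSMB8 at 52.5, 49.8 and 49.3 FPKM.

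With older symbols added, the lists gained genes of body position and signalling. Of 23 tested HOX and limb-position genes, 19 were higher in DPC and 3 in HMC (camera adjusted p = 2.32e-06, and adjusted p = 0.0893 with an estimated correlation). TBX15 (TBX14), a factor of dermal and limb mesenchyme, stood at 28.3 FPKM in DPC and 0.580 FPKM in HMC, HOXD8 (HOX4E) at 18.2 and 0.302 FPKM, and HOXC8 (HOX-3.1) at 21.4 and 1.33 FPKM. HOXA3 and PITX1 (BFT) were among those higher in HMC. The Hedgehog signal transducer SMO (SMOH) stood at 107 FPKM in DPC and 0.952 FPKM in HMC, and its target GLI1 (GLI) at 1.60 and 0.007 FPKM, while the target PTCH1 (PTCH) was higher in HMC, at 5.28 against 1.81 FPKM. The EGF receptor ligand HBEGF (DTR) at 79.9 FPKM in HMC against 0.759 FPKM and the bone matrix cytokine osteopontin (SPP1, in the table OPN) at 1504 FPKM against 7.99 FPKM were higher in HMC. The cell cycle inhibitor p21 (CDKN1A, in the table CIP1) was also higher in HMC, at 1141 FPKM against 76.4 FPKM.

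The class II genes were weighed against leukocytes in the HMC cultures. Cells that present antigen bring abundant leukocyte transcripts, but the median of the 12 other measured genes of the immune list was 0.0171% of the CD74 value in HMC. Among them AIF1 and CD14 were highest at 6.48 and 10.1 FPKM, both above DPC, TYROBP stood at 0.023 FPKM, and LAPTM5 was lower in HMC than in DPC. CSF1R (FMS) stood at 0.006 FPKM in HMC, and CD163 and CD207 (CLEC4K) at 0. The list mixes markers of several leukocyte types and holds no B cell marker, so its median cannot exclude leukocytes in general. These low values argue against the macrophages and Langerhans cells they mark, although AIF1 and CD14 go the other way. Other leukocytes stay open. A response to interferon-gamma, a known inducer of CIITA, stays open: 3 of its 5 tested target genes, TAP1, PSMB8 and PSMB9, were higher in HMC, while IRF1 was higher in DPC. Class II expression by the HMC themselves may be a biological difference between the cell types, a hypothesis these data cannot settle.

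Genes of the hair shaft and its regulators were low in HMC. The median of TCHH (THH), PRR9, HOXC13, FOXN1 (RONU), SELENBP1 (SBP) and CRYM was 1.18 FPKM in HMC, against 12.6 FPKM for all tested genes. For the hair keratins, of which KRT40 was highest at 2.17 FPKM, reads lost between near-identical genes stay open, because the counting of shared reads is not given in the sources used here. An epithelium of skin glands, rich in KRT7, KRT8, KRT18 and KRT19, is a candidate source of the HMC cultures, and the median of 6 gland genes was 0.233 FPKM, which decides nothing since late genes of both structures may be lost in culture. The difference between cultured HMC and the hair matrix in skin was not tested.

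Fibroblast transcripts were present in HMC, and an admixed share of DPC RNA or reads was weighed as their source. A single share would set all of them to 1 percentage of their DPC value, but over 23 fibroblast genes of at least 100 FPKM in DPC the median was 3.38%, and the 90th percentile was 5.4 times the 10th, at 7.24% and 1.34%. TWIST1 was at 0.764%, VIM at 6.97% and FN1, which is 1 of the 23, at 123%. SST, the gene with the lowest percentage, was at 0.117% of its DPC value in the mean of the HMC libraries. A single share cannot on average be larger than that and is argued against as the source of all of them. A share up to that size stays open, since none of the 1742 genes of at least 50 FPKM in DPC was at 0 in all 3 HMC libraries. The limit set by SST holds for RNA of DPC and not for other fibroblasts, which were not tested. Most of the 23 percentages were highest in HMC replicate 3, and those of THY1, COL3A1, SPARC, S100A4 and FN1 were not. TWIST1 was at 0.377, 0.87 and 1.046% in HMC replicates 1, 2 and 3, and SST stood at 4.75, 7.02 and 8.57 FPKM. The limit set by SST is therefore lower for HMC replicate 1 and higher for HMC replicate 3 than the mean gives. Low expression of the fibroblast genes by HMC is a candidate explanation for the rest and was not tested.

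The 6 samples allow 10 splits into groups of 3, too few for a share under 0.05. For the count of genes past the threshold, 1 split, the real one, gave 9020, and the highest of the others gave 0. For the 2-fold count that was also 1 split, with 3223 and 0. For the lists, 3 splits gave as many as the real 9, and the highest other gave 9. For the terms it was 1 split, with 48 and 43 for the highest other. Each other split divides the cell types unequally between its groups, so its contrast keeps part of the difference between DPC and HMC. Camera compares genes with each other and can find the same lists and terms there. The list and term counts of those splits are therefore not what groups unrelated to cell type would give. The rest of the difference between DPC and HMC falls within the groups of those splits and widens their spread. Few single genes can pass there, so the counts of 0 are no evidence on the real gene counts.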
